A study of Ovis aries with 7 samples.

How the data were processed

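Hypothalamic RNA of 3 fetuses after maternal ventilatory hypoxia and of 4 control fetuses was labelled with Cy3 and hybridised to Agilent sheep arrays, 1 colour and 1 array per fetus. Per the labels' protocols, RNA integrity numbers ranged from 7.4 to 8.4, cRNA yields from 4.29 to 10.38 µg, and dye incorporation lay between 9.0 and 12.8 pmol per µg, given as ranges over the samples. Groups and replicate numbers come from the sample titles. Per the file headers, the spot intensity values were extracted with Agilent Feature Extraction 10.1.1.1, which subtracted a fitted background, corrected for spatial trends and replaced signals not above background with a surrogate to give the processed intensity. The deposited value table holds the log2 of that processed intensity of the same array, equal within 5e-09 for each array, with no scaling between arrays, so its columns have different medians, 8.80 and 8.59 for hypoxia replicates 1 and 2. Its scale was therefore found from the values, and it has no direction or centring. The statistical test of the authors is not given in the sources used here.

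The reported values are log2 processed intensities minus the 75th percentile of each array's non-control spots. Outlier spots were left out on the array concerned (34 probe values), saturated spots were kept, control spots were left out, and spots of 1 probe were averaged. Probes well above background on at least 3 of 7 arrays were tested, without regard to group, which kept 12711 of 15008 probes. Hypoxia was compared with control in limma 3.58.1 (R 4.3.3), with lmFit and eBayes on the log2 scale, 2-sided, and Benjamini-Hochberg adjustment over the tested probes at 0.05. For a probe not well above background on any array of a group, the fold is a lower bound for the processed signal only, given without an error. It sets the mean of the brighter group against a mean for the dimmer group. Per array, the latter takes the higher of the lowest signal among probes well above background and the probe's own.

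Probes were named from RefSeq accessions (704 probes), gene IDs (125), symbols that the table of the ARS-UI_Ramb_v3.0 assembly also holds (484), synonyms (19), older symbols (1) or older names and descriptions in the files (247). Another 62 kept a symbol found only in the files, 67 had only a locus number and 13299 were unnamed here. A gene's probe was the one with the highest mean level over the 7 arrays, and values of other probes are given for some genes. Of 34 gene lists fixed before the data were examined, 23 had at least 5 measured genes and were tested with camera at a preset correlation of 0.01, against the other named genes, 898 in all, with Benjamini-Hochberg adjustment over the 23 lists and the result with an estimated correlation beside it. Markers of neurons, oligodendrocytes, lymphocytes, ependyma, erythroid cells and thalamus were among the 11 lists too small to test.

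The genes named were fixed by a rule. It took the 8 with the largest rise and the 8 with the largest fall past the adjusted threshold with separated groups, filled up by smallest unadjusted p where fewer passed, which here was all 16. It added 2 members of each list that was shifted without any member past the threshold, and a fixed set of endocrine, hypoxia, cytokine and cell type genes. Replicate numbers 1 to 3 occur in both groups, and nothing in the labels says that they pair fetuses. Slides were numbered with the hypoxia slide as 1.

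The procedure was tested on simulated data, 20 sets of 12711 probes for hypoxia against control with 200 probes changed. At an adjusted p under 0.05, 9.63% of probes changed 1.5-fold, 54.4% of those changed 2-fold and 90.0% of those changed 4-fold were recovered, and 5.79% of the calls were false. A list shifted by 0.4 on the log2 scale was found in 20 of 20 sets, while 15 of 440 tests of the other lists passed. Among list calls, these 15 thus stood beside 20 of the shifted list, so false list calls can be a large share. Any gene that another list shared with the shifted one was shifted there too, so some of the 15 may not be false. Simulated probes were independent of each other, which real probes are not. The number of arrays limits the precision.

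Alternatives were other scalings (median, quantile, 75th percentile over probes seen on all 7 arrays), normexp background correction with an offset of 50, the deposited log2 values, other filters on dim probes, slide as a random block, each control slide alone, a replicate block, leaving out each array, a trended and robust prior, array weights, an ordinary linear model, other thresholds and other list tests. For the random block, the trended prior and the ordinary model, the list test ran on the statistics of that fit. An alternative with all tested probes as the comparison set of the list test was added after the data were seen.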

Results

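Messenger RNA of the hypothalamus was measured in 7 late-gestation sheep fetuses on 1-colour oligonucleotide arrays, with 1 array per fetus. In 3 fetuses the ewe breathed a low-oxygen gas for 30 min and then normal gas for 30 min, and 4 control fetuses stayed at normal oxygen throughout. The hypothalamus, the brain region that drives the pituitary and the autonomic response to stress, was collected 60 min after the onset of hypoxia. Spots well above background made up 83.1% to 84.8% of the spots on the hypoxia arrays, against 77.2% and 80.8% for control replicates 1 and 2 and 85.2% and 86.4% for control replicates 3 and 4. The 75th percentile of the processed signal lay between 2024 and 2908 on all 7 arrays. The array held 15008 distinct probes, of which 1709 carried a gene symbol or locus name, so most of the transcriptome measured here had no gene name. The 3 hypoxia arrays shared slide 1, control replicates 1 and 2 shared slide 2, and control replicates 3 and 4 shared slide 3. Each slide had its own scan time.

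The main question was which hypothalamic transcripts differed after transient hypoxia. By gene group, 3 lists were higher and 3 lower in hypoxia among the 23 lists tested with camera, each with an adjusted p = 0.0468 at the preset correlation and an adjusted p = 0.765 with an estimated correlation, so that no list held with the latter. Genes of glutamate and GABA signalling, which carry fast excitation and inhibition between neurons, rose as a group, with a median log2 difference of 0.24 over 14 genes, 10 of them higher in hypoxia. Astrocyte markers rose, with a median of 0.45 over 7 genes, 6 of them higher, and 2 of these markers are also in the glutamate and GABA list. Immediate early and activity-dependent genes, the first to be transcribed after a stimulus, rose, with a median of 0.39 over 15 genes, 11 of them higher. Meningeal and fibroblast markers fell, with a median of -0.41 over 11 genes, 10 of them lower. Endothelial and pericyte markers fell, with a median of -0.20 over 9 genes, 8 of them lower, and cytosolic ribosomal proteins fell, with a median of -0.10 over 23 genes, 16 of them lower. The meningeal median was -0.20 without hypoxia replicate 1 and -0.23 without control replicate 4, the ribosomal one -0.06 without hypoxia replicate 3 and -0.02 without control replicate 4, and the astrocyte one 0.30 without hypoxia replicate 3. The immediate early median was 0.28 without hypoxia replicate 2. The mean level of the endothelial list, relative to each gene's mean, was -0.39 on hypoxia replicate 1. It was 0.02 and 0.01 on hypoxia replicates 2 and 3, within the range of the controls. Against slide 2 and slide 3 alone, the immediate early list did not pass in camera (adjusted p = 0.1595 and 0.1581). Without hypoxia replicate 1, control replicate 3 or control replicate 4, 0 lists passed, without control replicate 1 or 2, 1 and 2 did, and with quantile normalization 0 did.

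**Figure D1:**
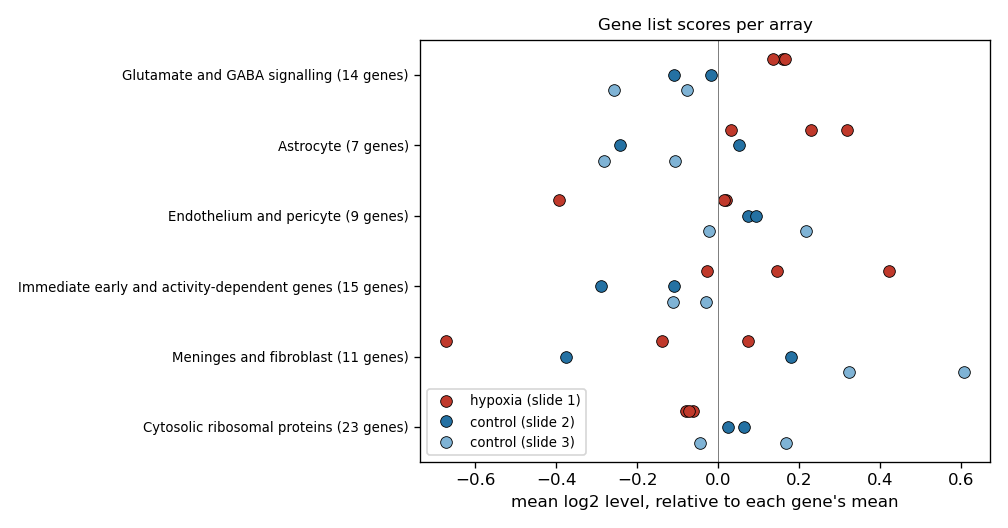
Scores of the 6 shifted gene lists on each of the 7 arrays. Each point is the mean log2 level of a list's genes on 1 array, relative to each gene's mean over the 7 arrays, with hypoxia arrays in red and the control arrays of slides 2 and 3 in dark and light blue. The meningeal and fibroblast scores of the 3 hypoxia arrays average -0.25, against 0.18 for the 4 controls. They overlap, with -0.67, -0.14 and 0.07 in hypoxia and -0.38 (control replicate 2) to 0.61 in the controls.

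Within the glutamate and GABA list, the metabotropic glutamate receptor gene GRM7 had a log2 difference of 0.68 (SE 0.13, adjusted p = 0.116) and SLC1A2, the main glutamate transporter of astrocytes, one of 0.76 (SE 0.20, adjusted p = 0.185). SLC1A2 is also an astrocyte marker, and the gap junction gene GJA1 of the same list had a difference of 0.46 (SE 0.14, adjusted p = 0.219). Among immediate early genes, CREM had a difference of 0.44 (SE 0.13, adjusted p = 0.215) and JUN one of 0.37 (SE 0.11, adjusted p = 0.225). Among the lower lists, the growth factor binding protein gene IGFBP2 and the collagen gene COL3A1 among meningeal markers had differences of -0.93 (SE 0.28, adjusted p = 0.225) and -0.82 (SE 0.34, adjusted p = 0.309). The endothelial receptor genes TEK and KDR had differences of -0.59 (SE 0.22, adjusted p = 0.279) and -0.51 (SE 0.24, adjusted p = 0.345). Without hypoxia replicate 1, TEK, KDR and COL3A1 had differences of -0.32, -0.25 and -0.45. Other probes of TEK gave -0.48 to -0.14, of KDR -0.62 to -0.33, of COL3A1 -0.70 to -0.21, of SLC1A2 0.38 to 0.86 and of CREM 0.28. The ribosomal protein genes RPL32 and RPSA had -0.64 (SE 0.14, adjusted p = 0.135) and -0.58 (SE 0.21, adjusted p = 0.276). None of these single genes passed the threshold over all 12711 probes. Adjusted over the list alone, GRM7 and SLC1A2 passed in the glutamate and GABA list, SLC1A2, GJA1 and SLC4A4 in the astrocyte list and RPL32 in the ribosomal list, while 0 genes passed in the immediate early, endothelial and meningeal lists.

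Probe by probe, 2 of 12711 probes passed an adjusted p of 0.05 in the limma fit, and neither carries a gene name. The probe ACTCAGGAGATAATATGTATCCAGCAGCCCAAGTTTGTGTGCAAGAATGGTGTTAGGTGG was 3.20-fold higher in hypoxia (log2 difference 1.68, SE 0.15), and the probe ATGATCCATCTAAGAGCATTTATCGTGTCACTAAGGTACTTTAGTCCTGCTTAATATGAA was 2.63-fold lower (log2 difference -1.40, SE 0.12), each with an adjusted p = 0.0474. At an unadjusted p under 0.05 there were 1990 probes, 1112 higher and 878 lower, where chance alone gives 635.6. In 16.2% of probes the 3 hypoxia values all lay on one side of the 4 control values, against 5.71% by chance. Leaving out 1 array gave 0 to 6 probes past the adjusted threshold, with 0 without control replicate 1, 3 or 4, 1 without any single hypoxia replicate and 6 without control replicate 2. Of the 2 probes above, 1 passed again without hypoxia replicate 2, and neither did without any other array. The remaining probes in these fits were different ones. Which side had more probes at an unadjusted p under 0.05 depended on the scaling and on the arrays used. With the deposited log2 values, which are not scaled between arrays, 660 of 981 were higher. It was 932 of 2001 with median scaling, 896 of 1943 with quantile normalization and 942 of 1982 with normexp and quantile normalization. With the reported scaling but without hypoxia replicate 3, it was 769 of 1643.

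The named genes with the smallest unadjusted p did not pass the adjusted threshold. On the higher side, KITLG, the stem cell factor, stood at 2.79-fold (log2 difference 1.48, SE 0.20, adjusted p = 0.0849), and its other probe at a log2 difference of 2.11. CD247, the T-cell receptor zeta chain, stood at 2.25-fold (log2 difference 1.17, SE 0.17, adjusted p = 0.0888). The other higher genes were GRM7, the motilin gene MLN, the chemokine gene XCL1, HOMER and CAMK2, which the array names only to family, and CYP3A24, with log2 differences of 0.68, 0.75, 0.75, 0.68, 0.47 and 0.94. The 2 probes of MLN disagreed, the other giving 0.01, and the other probe of CD3E, a lower gene, gave -0.50. On the lower side, IDH1, a cytosolic isocitrate dehydrogenase, was 1.99-fold lower. S100A4 and CD3E had log2 differences of -1.10 and -1.08, the protease inhibitor gene TIMP1 one of -0.74, RPL32 one of -0.64, CYBA, a subunit of the superoxide-producing NADPH oxidase, one of -0.55, and the lipid droplet gene PLIN2 one of -0.51. PADI3 was well above background on 3 of 4 control arrays and on 0 of 3 hypoxia arrays. On the processed signal this gives a bound of at least 1.66-fold lower in hypoxia (adjusted p = 0.109 in the limma fit). That bound carries no error and does not hold with normexp. With normexp, the log2 differences of MLN, PADI3, CYP3A24 and GRM7 shrank to 0.22, -0.15, 0.44 and 0.42, and that of KITLG to 1.09. Over these 16 genes the adjusted p ran from 0.0849 to 0.152, and in all of them the hypoxia values lay apart from the control values. The genes were chosen by smallest unadjusted p on the same arrays, so this separation largely follows from the choice.

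**Figure D2:**
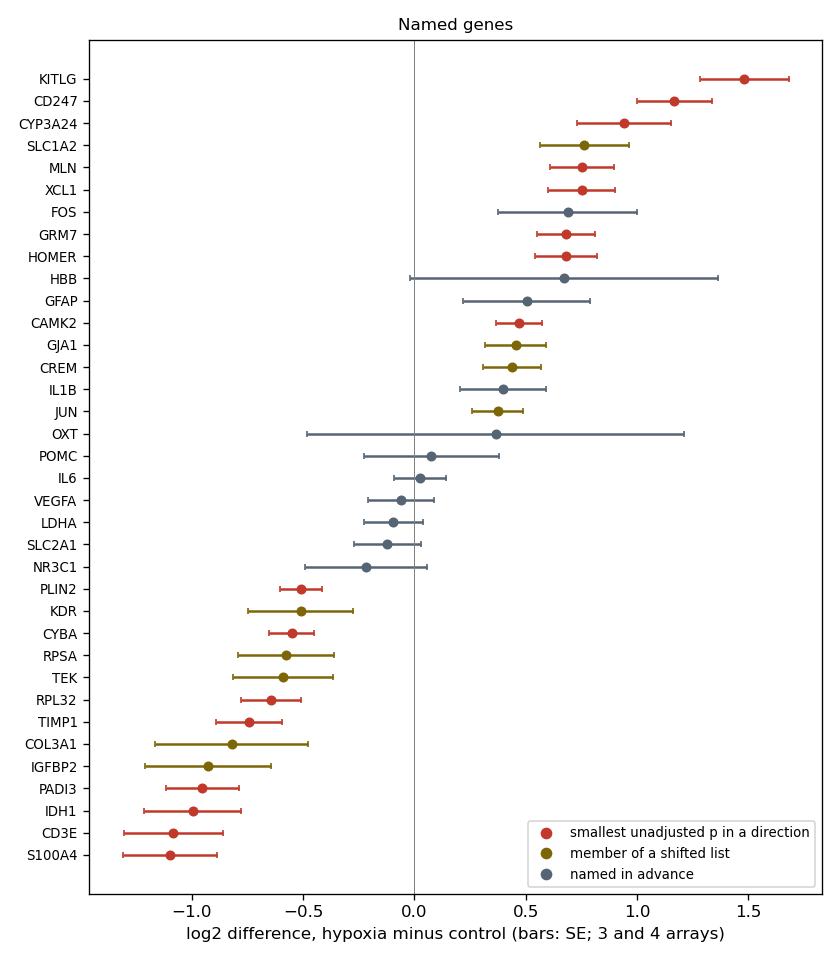
Log2 difference, hypoxia minus control, of the 36 named genes, with bars for the SE from the limma fit (3 hypoxia and 4 control arrays). KITLG has the highest value at 1.48 and S100A4 the lowest at -1.10, and none of the 36 passed the adjusted threshold.

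None of the genes named in advance passed the adjusted threshold. OXT, the oxytocin gene, had a log2 difference of 0.36 (SE 0.85) and POMC, the precursor of ACTH, one of 0.08 (SE 0.30). FOS, a marker of neuronal activation, had a difference of 0.69 (SE 0.31, adjusted p = 0.340), and its other 3 probes gave 0.90 to 0.93, while without control replicate 1 the difference was 0.41. The glucocorticoid receptor gene NR3C1 had a difference of -0.22 (SE 0.27). The hypoxia-inducible genes VEGFA, SLC2A1 and LDHA had differences of -0.06 (SE 0.15), -0.12 (SE 0.15) and -0.10 (SE 0.13). The other probes of POMC and LDHA had the opposite sign, at -0.01 and 0.01. The cytokine genes IL1B and IL6 had differences of 0.40 (SE 0.19) and 0.02 (SE 0.12), haemoglobin HBB one of 0.67 (SE 0.69) and the astrocyte gene GFAP one of 0.50 (SE 0.29). IL1B was at 0.22 without hypoxia replicate 1, GFAP at 0.31 without control replicate 1, and HBB at 0.29 and 1.35 without control replicates 2 and 4. The level of OXT was -1.12 on control replicate 4, against 1.84 to 2.57 on the other controls. Its difference ran from -0.55 to 1.28 over the alternatives. The directions of OXT, POMC, NR3C1, VEGFA, LDHA, IL6 and HBB turned under at least 1 alternative, whether in the processing or in the arrays used. AVP, CRH and MBP were not analysed here.

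The groups most often tied to hypoxia were not shifted as lists. HIF and hypoxia targets had a median log2 difference of 0.18 over 20 genes, 12 of them higher (adjusted p = 0.648), which was 0.12 without hypoxia replicate 2 and 0.07 without control replicate 1. Glycolysis and lactate transport had one of 0.16 over 12 genes (adjusted p = 0.734). Adjusted over the list alone, EDN1, which encodes the vasoconstrictor endothelin 1, and CITED2 passed among HIF targets, with log2 differences of 1.29 (SE 0.30) and 0.41 (SE 0.09). NFKBIA, the inhibitor of NF-kB, passed among 7 glucocorticoid-responsive genes at 1.40 (SE 0.38), a list with an adjusted p = 0.734. Likewise PSME2 passed among 5 proteasome genes at -0.41 (SE 0.10) and the transcription factor gene NEUROD1 among 9 pituitary markers at -0.60 (SE 0.14). These 5 genes and SLC4A4 were singled out after their values were seen. Genes of NF-kB and inflammatory cytokines had a median of 0.21 over 28 genes, 20 of them higher (adjusted p = 0.145). It was 0.08 without hypoxia replicate 2 and 0.36 without control replicate 4, and the list passed with normexp background correction (adjusted p = 0.0414). Interferon response genes had a median of -0.15 over 11 genes (adjusted p = 0.145). Hypothalamic neuropeptides stood at 0.01 over 17 genes and hormone receptors and prohormone processing at -0.02 over 27 genes (adjusted p = 0.988 for both). Neither had a steady direction: the neuropeptide median was 0.27 against control replicates 1 and 2 alone and -0.36 against control replicates 3 and 4 alone, and the hormone receptor median was 0.14 without control replicate 2. Microglia and macrophage markers had a median of 0.14 and a mean of 0.02 over 8 genes (adjusted p = 0.946), and the median was 0.06 without control replicate 1. Pituitary markers had a median of 0.34 and a mean of 0.01 over 9 genes (adjusted p = 0.946), and the median turned to -0.20 without control replicate 2 and to -0.36 against control replicates 3 and 4 alone, and was 0.04, 0.21 and 0.21 without hypoxia replicate 1, hypoxia replicate 3 and control replicate 1. The other 8 lists (cell cycle, antioxidant response, apoptosis, fatty acid oxidation, translation factors, proteasome, unfolded protein response and oxidative phosphorylation) had adjusted p from 0.210 to 0.946. Of these, cell cycle had a median of -0.25 over 10 genes, and without hypoxia replicate 3 it passed with a median of -0.52 (adjusted p = 0.0314), while the median was -0.15 without hypoxia replicate 2 or control replicate 3. In the proteasome, oxidative phosphorylation, translation factor and hormone receptor lists the median and the mean differed in sign.

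Slide was fitted as a random block because each slide held 1 group and the controls spanned 2 slides. It left 2 probes and 6 lists past the threshold, with an estimated correlation within slides of -0.03. That estimate is negative, so the block made no allowance for slide differences. The fit had 2148 probes at an unadjusted p under 0.05, against 1990 without the block. With 1 group on each slide it cannot separate slide from hypoxia. Against control replicates 1 and 2 alone, 232 probes (219 higher and 13 lower) and 0 lists passed, with 86 of the 232 among the 1276 probes not well above background on all 7 arrays. Against control replicates 3 and 4 alone, 4 probes and 4 lists (ribosomal, glutamate and GABA, astrocyte and meningeal) passed.

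The control slides compared with each other show how far arrays of 1 group can differ. Pituitary markers, hypothalamic neuropeptides and meningeal markers were higher as groups on slide 3 than on slide 2, with median log2 differences of 0.86, 0.55 and 0.38 (adjusted p = 0.0423 for each). With an estimated correlation none of these held (adjusted p = 0.957 with an estimated correlation). In limma, 2 of 12694 probes passed the adjusted threshold, and 1015 had an unadjusted p under 0.05 where chance gives 634.7. With normexp background correction 1998 did, more than the 1724 for hypoxia against control in that setting. With 2 arrays against 2 the precision is low. Arrays of 1 slide correlated at 0.985 to 0.990 over probes, controls across slides at 0.983 on average, and hypoxia arrays at 0.980 with slide 2 and 0.986 with slide 3 on average.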

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

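The tests of slide differences were chosen after the results they concern had been seen, while the counts over other splits and the test of signal over background were fixed before. Among 69 sets of 4 control values, 3 had a value standing apart from the other 3, and chance gives about 3.45. The level of CD3E, a T-cell gene, was -2.42 on control replicate 2, against -3.35 to -3.20 on the other controls. The mean score of fatty acid oxidation and ketone metabolism was -0.0469 on control replicate 3, against 0.02 to 0.04. The level of the prolactin gene PRL was 1.13 on control replicate 4, against -3.80 to -3.46.

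The hypoxia arrays differed from the controls in 1990 probes at an unadjusted p under 0.05. Of the 35 splits of the 7 arrays into 3 and 4, 1 gave as many, the real one, and the highest other gave 1667 (control replicates 1, 2 and 3 against the rest). That share is under the 0.05 set beforehand, but 1 of 35 is the smallest these splits can give. Arrays that share a slide are also not freely exchangeable, so chance sorting is less likely for this count but not excluded. For the 6 shifted lists at the preset correlation, 1 of 35 splits gave as many and the highest other gave 4. This is again the smallest share possible, with the same limits. With an estimated correlation 0 lists passed (adjusted p = 0.765). For the 2 probes past the adjusted threshold, 3 of 35 splits gave as many and the highest other gave 2, so chance is not excluded. The real split is also the only one that follows a slide. Beyond the spread within slides, the mean square difference between the control slides was 0.675 of the average between the hypoxia slide and the control slides. It was 0.0781 between the control slides, 0.156 for hypoxia against slide 2 and 0.0756 against slide 3. By this measure the hypoxia arrays were no farther from slide 3 than the control slides were from each other. Scan time differed by slide and cannot be told from slide or group. A slide difference and an effect of hypoxia both stay open, since they cannot be told apart with 1 slide of hypoxia arrays. Part of the difference between the control slides may come from low signal. The share at an unadjusted p under 0.05 was 0.0671 among probes seen on all 7 arrays, within the bound set beforehand, and 0.195 among the others. A dim probe that is lower on 1 control slide can fall among the others through that difference itself. The higher share there is thus partly built in and does not show that low signal is the source.

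Meningeal and endothelial markers were lower in the hypoxia group, with medians of -0.41 and -0.20, and without hypoxia replicate 1 with medians of -0.20 and -0.17 (adjusted p = 0.393 and 0.320). The mean endothelial score was -0.39 on hypoxia replicate 1 but 0.02 and 0.01 on hypoxia replicates 2 and 3. Those of replicates 2 and 3 lay within the -0.02 to 0.22 of the controls, so the lower mean rests largely on 1 fetus. For the meningeal list a slide difference is a candidate explanation, since its mean differed between the control slides by 0.56 (SE 0.31), 1.31 times the size of the -0.43 between hypoxia and control, and against slide 2 alone its median was -0.12 (adjusted p = 0.631). For the endothelial list the mean differed between the control slides by 0.01 (SE 0.12) against -0.21, a ratio of 0.0566 that is too uncertain with 2 arrays a slide to exclude a slide difference, and its medians were -0.17 and -0.22 against each control slide alone. Less meningeal and vessel tissue in the hypoxia samples stays open: 18 of the 20 members of both lists had a difference below 0, as did 9 of the 10 with brighter probes (IGFBP2 -0.93, IGF2 -1.28 and PTGDS -0.04 among them), but this restates that the lists were lower and supports no cause. A response of vessels and meninges to hypoxia also stays open, untested.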

How the results depend on the processing

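All 6 shifted lists kept the direction of their medians in 22 of 22 alternative fits. They passed the threshold in 6 (ribosomal) to 11 (glutamate and GABA, astrocyte) of them. The ribosomal median was -0.02 without control replicate 4 and against slide 2 alone. The slide block, the trended robust prior and the ordinary linear model leave the differences as reported, so no direction could turn there. The replicate block gave the same medians as leaving out control replicate 4. All 22 fits reuse the same arrays and are not separate tests. By the 1 probe chosen per gene, 29 of 36 named genes kept their direction in every alternative, and KITLG passed the threshold in 4 and CD247 in 3. Through another probe, HOMER passed with normexp and quantile normalization, and HOMER, CYBA and TIMP1 passed with the trended robust prior. With normexp, KITLG, MLN, PADI3, CYP3A24, GRM7 and TEK moved by more than the SD between arrays. Probes changed numbered 2 as reported, and 0 with the 75th percentile over probes seen on all 7 arrays, no filter on dim probes or an ordinary linear model. They numbered 10 with normexp, 35 with normexp and quantile normalization, 10 with the deposited log2 values, 25 with probes above background on all 7 arrays, 232 and 4 against the first control slide (slide 2) and the second (slide 3) alone, 57 with a trended robust prior, 4 with array weights and 39 at an adjusted p under 0.10. With a replicate block, which leaves control replicate 4 without a partner and so without weight, 0 probes and 0 lists passed, as many as without that array and no block. Same-numbered fetuses deviated together with correlations of 0.12, 0.09 and 0.11, not all above the 0.1 set for pairing, though each hypoxia array correlated best with the control of its own number. Probes at an unadjusted p under 0.05 numbered 981 with the deposited values, 660 of them higher, against 1112 of 1990 as reported, while most were lower with median scaling (932 of 2001 higher), quantile normalization (896 of 1943) or both normexp and quantile normalization (942 of 1982) and without hypoxia replicate 3 (769 of 1643). Lists shifted numbered 6 as reported, 0 with quantile normalization, the 75th percentile over probes seen on all 7 arrays, the deposited values, the first control slide alone, an ordinary linear model, the mean of all probes per gene or an estimated correlation, 1 with normexp and quantile normalization and 3 with probes above background on all 7 arrays. With the comparison set added later there were also 6. Leaving out 1 array gave 0 to 6 probes changed, 1326 to 2090 probes at an unadjusted p under 0.05 and 0 to 5 lists. Without hypoxia replicate 1 there were 1 probe, 1326 probes at an unadjusted p under 0.05 and 0 lists. Without control replicate 1 there were 0 probes and 1 list, without control replicate 2, 6 probes and 2 lists, and without control replicate 3 or 4, 0 probes and 0 lists. Without hypoxia replicate 2 or 3, 1 probe passed. Between the control slides, 2 probes passed as reported, 5 with quantile normalization and 17 with normexp. The cause of these differences was not tested. Signal over background limits dim probes, and control replicate 1 had 77.2% of spots well above it.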

Other observations

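The pituitary hormone genes CGA and TSHB varied more between fetuses than between groups, while LHB had a log2 difference of 0.39 (SE 0.13) that did not pass the adjusted threshold. CGA, the common alpha subunit of pituitary glycoprotein hormones, spanned -6.47 (control replicate 2) to 1.39 (control replicate 3) on the log2 scale, and TSHB, the thyrotropin beta subunit, followed it over the 7 arrays (Pearson r = 0.972, exact permutation p = 0.000198, the smallest the permutations can give, adjusted over 3 relations 0.000595; Spearman rho = 1.00, exact permutation p = 0.000397, adjusted 0.00119). TSHB was not well above background on control replicate 2 and hypoxia replicate 2, which are also the arrays farthest from the median of CGA, and without them r was 0.973 over 5 arrays. Hypoxia minus control was 0.75 (SE 1.97) for CGA and 0.76 (SE 1.40) for TSHB.

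A hypothesis formed after these values were seen is that pituitary tissue of 1 makeup was attached to some of the dissected samples. PRL, abundant in the anterior pituitary, would then follow CGA, and it did not (Spearman rho = -0.29, exact permutation p = 0.556), with the highest PRL level, 1.13, on control replicate 4, where CGA was -2.50. Attached tissue that differs in makeup, such as the part of the pituitary along the stalk, may remain an explanation and was not tested.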
